A study of Mus musculus with 12 samples.

How the data were processed

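Gene expression was measured by sequencing of RNA from mouse liver after injection of concanavalin A (Con A), with or without mesenchymal stromal cells (MSC), at 6 h and 12 h. Per the labels, RNA was extracted from liver tissue with Trizol, mRNA was captured with oligo(dT) beads, cDNA was primed with random hexamers, and the libraries were circularized single-strand libraries. The series text speaks of RNA from hepatocytes where the sample labels give liver tissue; the values are described here as whole liver RNA. The labels state neither the strandedness of the libraries nor the species of the MSC. For the 12 libraries the study deposited 4 tables, 1 for each group, with 3 columns each.

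The deposited tables hold whole-number counts for each gene, and a check of every value found no fractions, negative values or rescaled columns, so the counts were read as raw and unnormalized. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, StringTie 2.1.2 and the assembly GRCm39; the program that made the counts and the gene annotation are not given in the sources used here. Each table has 23574 entries in the same order of content. Of these 1715 are loci numbered by StringTie (MSTRG), 26 carry Ensembl gene numbers, and 21437 have symbols found in GENCODE M21 (GRCm38), the reference used here for gene names, neighbourhood, length and GC content. Statements on neighbouring or overlapping genes refer to that annotation and not to the one used for counting.

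Samples were placed in groups by the labels alone: Con A and Con A + MSC, each at 6 h and 12 h, with 3 libraries per group. Library totals ran from 29.7 to 36.1 (in units of 1e6 counts). A count of 0 in a library excludes, with 95% confidence, levels above about 3 counts, which is between 0.0657 and 0.119 CPM (counts per 1e6 counts); this floor of 3 counts per library was used for genes absent from a whole group. Entries with too few counts were removed with filterByExpr by group, which left 14275 for testing and 9299 untested. TMM factors scaled the libraries, and CPM in the text use these factors.

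All 12 libraries entered 1 fit with a mean for each of the 4 groups (8 residual degrees of freedom). The edgeR 4.0.16 quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) was run for MSC against no MSC at 6 h and at 12 h, for 12 h against 6 h without and with MSC, and for the difference of the MSC effect between the times. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05 and no fold threshold. Standard errors were taken as the size of the log2 change divided by the square root of the F statistic. For genes, the verbs rose and fell are used only where they passed in the fit or setting named. Where the text says adjusted over the list alone, the p-values were adjusted over the genes of that list, with the same threshold. These tests, the gene lists, the named genes and most alternatives were fixed before the data were examined.

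Named genes followed a rule. For each MSC comparison these are the 10 largest rises and 10 largest falls among passing genes with a symbol that is not a predicted or RIKEN name, with 3 libraries all on 1 side of the other 3, and with at least 5 CPM in the higher group. Where fewer than 5 passed in a direction, the list was filled to 5 with the smallest unadjusted p, described as not passing. For the time comparisons and the difference of the MSC effect the number was 5. A panel of 30 genes was set for report whatever its result, and up to 4 members with the smallest adjusted p were named for a list. Genes named outside the rule, such as other genes of the 2 smallest sets of calls and genes of the chromosome 4 run, were chosen after their values were seen. Some genes that these rules pick are not reported here.

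There were 52 gene lists with 814 genes, written from textbook knowledge of liver, immune and stress biology and not from these samples; 796 of the genes are in the tables and 747 were tested. Lists with at least 5 tested genes (51) were tested with camera (limma 3.58.1), two-sided, with the preset correlation between genes of 0.01 and again with a correlation estimated for each list, adjusted over the lists of a comparison. Some genes belong to more than 1 list. Marker lists are read as RNA of marker genes in whole liver, not as numbers of cells.

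Principal components used log2 CPM (prior count 2) of the 500 genes with the highest variance, each centred. Distances between libraries were compared within and between groups with an exact permutation test. It gives the share of splits with an equal or larger difference and cannot go below 0.1 with 10 splits. Other splits of the libraries were refitted in the same way: all 10 for each pair of groups and 100 drawn at random for the difference of the MSC effect.

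The procedure was tested on simulated data before use. With true changes of 2-fold and 4-fold in counts of similar depth and spread, it recovered 32.8% and 75.8% of genes at 6 h, 43.3% and 75.8% at 12 h, and 0% and 57.6% for the difference of the MSC effect. It called 4, 5 and 0 unchanged genes out of 13962, 13957 and 13960. It recovered 5 of 5 changed lists in each of the 4 group comparisons and 3 of 5 for the difference. Of lists without changed genes it called 2 of 36 for MSC at 12 h and 0 in the other comparisons. The simulated genes were drawn independently of each other, so these list results do not cover lists whose genes move together. Per comparison 67 genes were changed by 2-fold and 66 by 4-fold, so recovery may differ where many more genes change.

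Alternatives were no filter on low counts, at least 5 CPM in at least 3 libraries, a 2-fold minimum, DESeq2 1.42.0, its size factors within edgeR, only the libraries of the groups compared, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were scaling by total count alone, the mitochondrial share of each library as a covariate, and a fit without the 13 mitochondrially encoded genes. Untested entries and the 4 sex chromosome genes, too few for a list test, were left out of the tests. R 4.3.3, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.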

Results

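Liver RNA was sequenced from C57BL/6 wild-type mice given concanavalin A (Con A), a plant lectin that activates T cells and injures the liver, with or without mesenchymal stromal cells (MSC). Livers were taken at 6 h or 12 h, which makes 4 groups of 3 libraries: Con A 6 h, Con A + MSC 6 h, Con A 12 h and Con A + MSC 12 h. The tables hold whole-number counts for 23574 genes and assembled loci, of which 14275 had enough counts to be tested. Library totals, in units of 1e6 counts for replicates 1 to 3, were 33.5, 31.2 and 30.5 (Con A 6 h), 30.9, 31.5 and 31.3 (Con A + MSC 6 h), 31.1, 31.0 and 29.7 (Con A 12 h) and 30.3, 35.4 and 36.1 (Con A + MSC 12 h). A gene with 3 counts in a library lay between 0.0657 and 0.119 CPM (counts per 1e6 counts). The design has no mice without Con A, so every value compares injured livers with injured livers. For the same reason a change from 6 h to 12 h cannot be told apart from a change with time of day. The labels do not say whether the replicates are separate animals; if they are not, the p-values measure only the spread between these samples.

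The time point (6 h or 12 h) separated the libraries far more than MSC did. On the first principal component of the 500 most variable genes (59.2% of the variance), the 6 h libraries lay between -42.4 and -26.4 and the 12 h libraries between 30.4 and 40.1. The second component (10.1%) spread the 12 h libraries. Con A 12 h replicates 2 and 3 had scores of 22.7 and 30.4, Con A + MSC 12 h replicates 2 and 3 had -21.8 and -21.0. The replicate 1 libraries of both groups lay between them at -1.24 and -7.26. Mean distances between libraries exceeded those within groups by 0.0641 (MSC at 6 h), 0.171 (MSC at 12 h), 0.619 (time without MSC) and 0.593 (time with MSC) log2 CPM per gene. In each of the 4 comparisons the exact permutation p (equal or larger differences) was 0.1, the smallest that 10 splits of 6 libraries can give. Mitochondrially encoded genes made up 5.59%, 17.3% and 24.9% of the counts in the 3 Con A 12 h libraries. They made up 7.74 ± 1.49% (mean ± SD, n = 3) in Con A + MSC 12 h, 9.79 ± 2.01% in Con A 6 h and 11.5 ± 0.567% in Con A + MSC 6 h, so this share varied most within the group without MSC at 12 h.

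**Figure D1:**
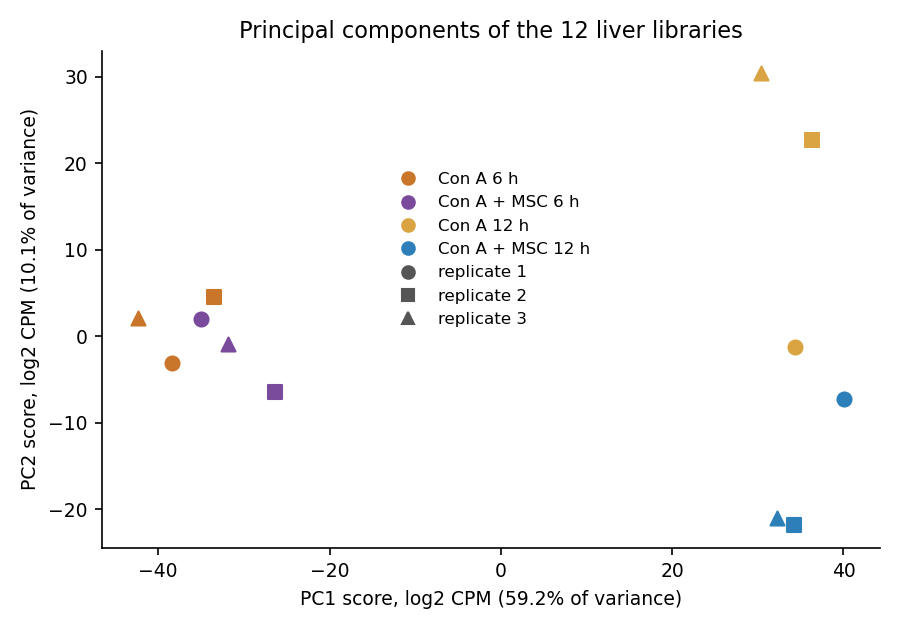
Scores of the 12 libraries on the first and second principal components of log2 CPM (500 most variable genes, each centred); colours give the group and symbols the replicate number. The 6 h libraries lie below -26.4 on the first component and the 12 h libraries above 30.4, and the replicate 1 libraries at 12 h lie at -1.24 (without MSC) and -7.26 (with MSC) on the second.

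At 6 h, the livers with MSC held less RNA of interferon-stimulated genes. Isg15, which encodes a ubiquitin-like protein that is attached to other proteins during antiviral responses, and Usp18, the protease that removes it and dampens interferon receptor signalling, both fell. The related antiviral genes Dhx58 and Ddx60, which act in the sensing of foreign RNA, fell with them, as did Tor3a. Other genes fell too, and whether they belong to this programme was not tested. They included Slc25a22, a mitochondrial glutamate carrier, Lmo2, a transcription cofactor of blood and endothelial cells, and Adprh, which removes ADP-ribose from proteins. Cyth1, a regulator of cell adhesion, and Pik3c2g, a lipid kinase of the liver, fell as well. Nat8, an acetyltransferase found in liver and kidney, rose. Isg15 had 93.5 ± 23.8 CPM with MSC and 585 ± 261 CPM without (mean ± SD, n = 3 per group; log2 -2.64 ± 0.37 SE, edgeR adjusted p = 0.0186). Usp18 had 84.4 ± 25.8 against 414 ± 180 CPM (log2 -2.29 ± 0.35, edgeR adjusted p = 0.0331). Slc25a22 had 97.6 ± 8.76 against 275 ± 60.2 CPM (log2 -1.50 ± 0.19, edgeR adjusted p = 0.0115). Lmo2 had 4.00 ± 0.486 against 21.5 ± 8.66 CPM (log2 -2.43 ± 0.31, edgeR adjusted p = 0.0115). Nat8 had 6.43 ± 1.57 against 1.55 ± 0.316 CPM (log2 2.06 ± 0.33, edgeR adjusted p = 0.0438). The log2 changes of the others were -2.75 (Ddx60), -2.57 (Tor3a), -2.45 (Dhx58), -1.94 (Pik3c2g), -1.47 (Adprh) and -0.92 (Cyth1), with adjusted p between 0.0161 and 0.0438. Rtkn, Dsc2, Cad and Megf9, with log2 differences of 1.49, 1.01, 1.21 and 1.17, had the next smallest p-values among higher genes and did not pass (adjusted p = 0.0530 for each).

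In all, 14 of 14275 genes passed at 6 h, 3 higher and 11 lower with MSC, and 1561 had an unadjusted p below the threshold where chance would give 714. The groups did not overlap in 16.6% of genes, where chance gives 10%. The 14 included the assembled loci MSTRG.15211 (log2 7.80) and MSTRG.10311 (log2 -4.59), and Gm45717 (log2 8.06). All exon bases of Gm45717 are shared with Ifitm2 (54.1%) and Ifitm5 (45.9%) on the same strand in GENCODE M21 (GRCm38), so its counts cannot be assigned to it with certainty. The number passing was unstable: leaving out Con A replicate 1, 2 or 3 gave 236, 11 and 1, and leaving out Con A + MSC replicate 1, 2 or 3 gave 3, 2 and 1. Isg15 lost its call without any library but Con A replicate 1, with adjusted p between 0.0536 and 0.178; each other named gene that passed lost its call without 4 or 5 of the 6 libraries. With DESeq2, 307 genes passed (75 higher, 232 lower). In a fit of the 6 h libraries alone 2 passed, both higher, so each of the 11 lower genes lost its call (edgeR adjusted p = 0.0769 for Isg15, 0.106 for Usp18 and 0.145 for Ddx60). With the replicate number as a block 4 passed, 2 of them lower, and Isg15 (0.0682), Usp18 (0.0953) and Ddx60 (0.113) did not.

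As a set, the type I interferon response genes, which cells switch on when interferon alpha or beta binds its receptor, were the list farthest below the other genes at 6 h with MSC. Of its 18 tested genes 2 fell (Isg15 and Usp18) and 16 did not pass over all genes; adjusted over the list alone, 18 fell. Ddx58, an RNA sensor, had 31.4 ± 8.24 against 108 ± 55.8 CPM (log2 -1.79 ± 0.31, edgeR adjusted p = 0.0511). Cmpk2, a nucleotide kinase, had 32.3 ± 19.3 against 538 ± 414 CPM (log2 -4.06 ± 0.72, edgeR adjusted p = 0.0530). The median log2 change was -2.11 (camera adjusted p = 1.2e-40; adjusted p = 0.258 with an estimated correlation). It was -1.45 without Con A 6 h replicate 2, the library with the highest interferon level, and between -2.49 and -1.90 without any of the other libraries. Leukocyte markers pooled over 7 lists (80 genes) had a median of -0.0457 in the same comparison. The interferon gamma response, driven by the interferon that activated T cells and natural killer cells release, differed little: 0 of 23 genes passed, 0 when adjusted over the list alone. Their median change was -0.19 (camera adjusted p = 0.0279; adjusted p = 0.867 with an estimated correlation). Its camera p did not pass without Con A replicate 1 (0.0647) or 3 (0.118), or without Con A + MSC replicate 2 (0.309) or 3 (0.0939).

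**Figure D2:**
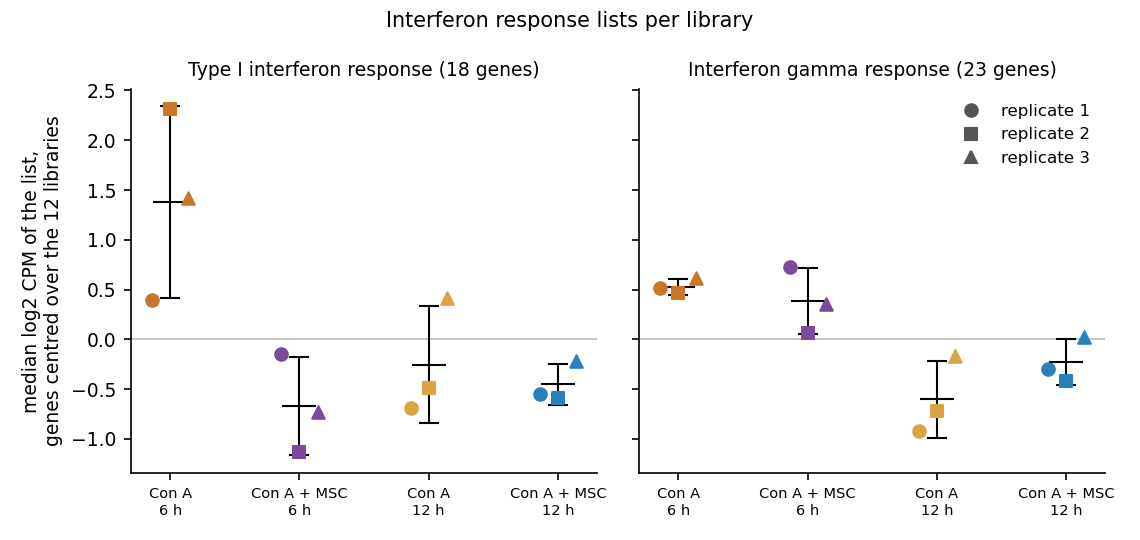
Median log2 CPM of the type I interferon response (18 genes) and the interferon gamma response (23 genes) in each library, each gene centred over the 12 libraries. Symbols are libraries, and lines show the mean and SD of 3. For type I interferon genes the Con A 6 h libraries lie at 0.39, 2.32 and 1.42 and the Con A + MSC 6 h libraries at -0.15, -1.13 and -0.73.

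Other inflammatory lists were also lower as sets with MSC at 6 h, while none of their genes passed over all genes. Neutrophil markers were lower with them: 0 of 19 passed, 0 adjusted over the list alone, median -0.54 (camera adjusted p = 0.00335; adjusted p = 0.761 with an estimated correlation). Their camera call ended without Con A 6 h replicate 3 (0.121) or Con A + MSC 6 h replicate 2 (0.192). For cytokines of myeloid cells, which carry inflammatory signals between leukocytes, 0 of 15 genes passed and 2 fell when adjusted over the list alone. Their median was -1.19 (camera adjusted p = 1.9e-09; adjusted p = 0.258 with an estimated correlation), with Csf3, a growth factor of neutrophils, at 3.06 ± 2.43 against 20.5 ± 9.86 CPM. Of 18 chemokines, which attract leukocytes, 0 passed and 7 fell when adjusted over the list alone. The chemokine median was -1.02 (camera adjusted p = 7.8e-06; adjusted p = 0.376 with an estimated correlation); Ccl5 had 2.45 ± 1.17 against 22.3 ± 7.31 CPM (log2 -3.18 ± 0.60, edgeR adjusted p = 0.0530). NF-kB targets (16 genes, 4 fell adjusted over the list alone, median -0.49) had a camera adjusted p of 4.3e-06, and adjusted p = 0.258 with an estimated correlation. Apoptosis and p53 targets (20 genes, 2 fell adjusted over the list alone, median -0.57) had 2.3e-07, and adjusted p = 0.332 with an estimated correlation. Cholesterol synthesis genes, which make sterols from acetyl-CoA, were higher: 0 of 21 passed, 0 adjusted over the list alone, median 0.57 (camera adjusted p = 1.3e-08; adjusted p = 0.566 with an estimated correlation). Hmgcs1 had 178 ± 68.2 against 76.3 ± 34.0 CPM. In total 21 of 51 lists passed camera at 6 h, 6 higher and 15 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.258).

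None of the 29 panel genes tested passed at 6 h; Il4 was not tested, with 0 to 4 counts per library. The log2 differences with MSC were -0.74 (Ifng), -1.27 (Tnf), -1.75 (Il6), -0.97 (Il1b), -2.05 (Il10), -0.87 (Cxcl1), -1.46 (Cxcl2), 0.03 (Cxcl9), -0.23 (Cxcl10) and -1.14 (Ccl2). For neutrophil and acute-phase genes they were -0.60 (S100a8), -0.75 (S100a9), -0.32 (Lcn2), -0.32 (Saa1) and -0.39 (Saa2). For signalling and stress genes they were -0.38 (Socs3), -0.64 (Cdkn1a), 0.22 (Hmox1), -0.18 (Mt1), -0.16 (Mt2) and 0.04 (Gpx4). Cell cycle and hepatocyte genes gave -0.33 (Ccnd1), -0.07 (Mki67), -0.29 (Alb), 0.14 (Cyp2e1), 1.58 (Cyp7a1), -0.02 (Cyp3a11) and -0.46 (Pck1). The smallest adjusted p was 0.195 (Cdkn1a, edgeR). Cxcl9, a chemokine induced by interferon gamma, had 6234 ± 1328 CPM with MSC and 6115 ± 824 CPM without.

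At 12 h, livers with MSC held more RNA of marker genes of the cells that line and surround the sinusoids than livers without MSC. Dnase1l3, a nuclease secreted by sinusoidal endothelium and macrophages, the endothelial growth factor receptor Kdr and the collagens Col1a1 and Col3a1 of stellate cells rose. Marco, a scavenger receptor, Cd5l, a secreted macrophage protein, and Adgre1, which encodes the F4/80 antigen, rose as markers of Kupffer cells, the resident macrophages of the liver. Ciita, the master regulator of MHC class II genes, and Cd74, the chaperone of MHC class II molecules, rose as well. Of 16 sinusoidal endothelial markers 7 rose, 0 fell and 9 did not pass (12 rose adjusted over the list alone); the median was 1.42 (camera adjusted p = 6.9e-11; adjusted p = 0.208 with an estimated correlation). Dnase1l3 had 29.7 ± 5.43 CPM with MSC and 5.26 ± 2.06 CPM without (log2 2.50 ± 0.35, edgeR adjusted p = 0.00667). Kdr had 5.30 ± 1.30 against 1.09 ± 0.379 CPM, and Oit3 and Gpr182 changed by 2.44 and 1.64. Of 19 stellate cell and matrix genes 7 rose, 0 fell and 12 did not pass (12 rose adjusted over the list alone). The median log2 change was 1.16 (camera adjusted p = 4.6e-10; adjusted p = 0.208 with an estimated correlation). Col3a1 rose by log2 2.27 (SE 0.41, edgeR adjusted p = 0.0156), Lum changed by 2.70, Tgfb1 by 1.45 and Col1a1 by 2.46. Of 12 Kupffer cell markers 3 rose and 9 did not pass (9 rose and 1 fell adjusted over the list alone). The list median was 1.70 (camera adjusted p = 1.6e-05; adjusted p = 0.394 with an estimated correlation). Cd5l had 12.1 ± 3.40 against 1.46 ± 0.681 CPM (log2 3.03 ± 0.66, edgeR adjusted p = 0.0300). Of 8 MHC class II genes 4 rose and 4 did not pass (7 rose adjusted over the list alone). Their median change was 1.14 (camera adjusted p = 1.2e-08; adjusted p = 0.208 with an estimated correlation). Ciita had 9.86 ± 1.96 against 2.13 ± 1.17 CPM (log2 2.22 ± 0.39, edgeR adjusted p = 0.0151), and Cd74 had 74.0 ± 15.3 against 23.7 ± 12.5 CPM. Without Con A 12 h replicate 2 the numbers that rose were 1 (endothelial), 1 (stellate), 0 (Kupffer) and 0 (MHC class II), and with any other library left out they reached 7, 9, 3 and 7 at most. Calls did not hang on that library alone. Over all genes 327 were higher with MSC, against 39 without it and 71 and 37 without Con A + MSC 12 h replicate 2 or 3. With the mitochondrial share as a covariate the numbers that rose in the 4 lists were 3, 2, 0 and 5, with medians of 1.60, 1.30, 1.90 and 1.86. Neutrophil markers did not move with these lists: 0 of 19 passed, 0 adjusted over the list alone, median -0.11 (camera adjusted p = 0.859, and 0.952 with an estimated correlation). Their median was 0.17 with scaling by total count and 0.37 with the mitochondrial share as a covariate, so its sign depends on the setting. From 6 h to 12 h without MSC the median log2 changes were -1.08 (endothelial), -0.86 (stellate) and -1.90 (Kupffer). With MSC they were 0.29, 0.51 and -0.37. Scaling by total count gave -0.77, -0.62 and -1.63 without MSC and 0.83, 1.05 and 0.18 with MSC. The lower level at 12 h without MSC was thus seen with both scalings.

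**Figure D3:**
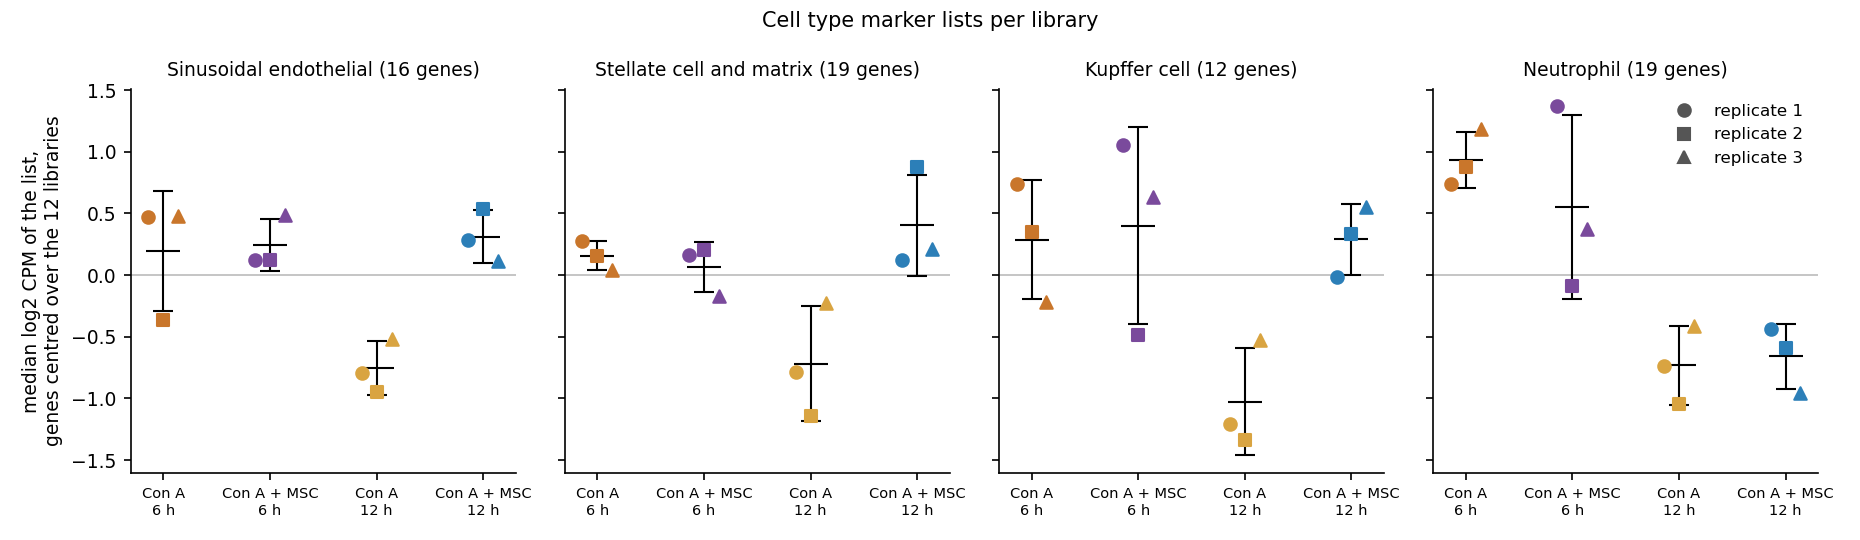
Median log2 CPM of 4 marker lists in each library, each gene centred over the 12 libraries. Symbols are libraries, and lines show the mean and SD of 3. Con A 12 h libraries lie lowest for sinusoidal endothelial (-0.79, -0.95 and -0.52), stellate (-0.79, -1.14 and -0.22) and Kupffer cell lists (-1.21, -1.34 and -0.53), whereas for neutrophil markers both 12 h groups lie below 0.

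Among the genes that fell with MSC at 12 h were metallothioneins and immediate early genes. The metallothioneins Mt1 and Mt2, which bind zinc and are induced in the inflamed liver, fell. Mt1 went from 9159 ± 3861 to 2205 ± 881 CPM (log2 -2.05 ± 0.36, edgeR adjusted p = 0.0151) and Mt2 went from 5201 ± 1907 to 1412 ± 412 CPM (log2 -1.88 ± 0.30, edgeR adjusted p = 0.0109). Of 16 metallothionein, iron and heme genes 4 fell, 0 rose and 12 did not pass (5 fell adjusted over the list alone). They included Hamp, the iron hormone hepcidin, with 359 ± 226 against 1292 ± 647 CPM, and Ftl1, a ferritin chain (log2 -0.83). Their median was -0.27 (camera adjusted p = 4.8e-04; adjusted p = 0.208 with an estimated correlation), and without Con A + MSC 12 h replicate 3 the number that fell was 0. With the mitochondrial share as a covariate it was 1, and with scaling by total count it was 2 and the median -0.02. Of 18 immediate early genes, transcription factors and regulators induced within minutes of a stimulus, 5 fell and 13 did not pass (12 fell adjusted over the list alone). The median log2 change was -1.13 (camera adjusted p = 2.0e-08; adjusted p = 0.364 with an estimated correlation). Jund had 70.6 ± 14.0 against 182 ± 24.0 CPM (log2 -1.37 ± 0.19, edgeR adjusted p = 0.00667), and Maff, Btg2 and Ier3 changed by -1.54, -1.28 and -1.35. Without Con A 12 h replicate 2 the number that fell was 2, and with the mitochondrial share as a covariate it was 3 and the median -0.35. Of 18 hypoxia and glycolysis genes 2 fell, Adm among them, and 16 did not pass (2 rose and 8 fell adjusted over the list alone). The list median was -0.41 (camera adjusted p = 8.6e-04; adjusted p = 0.515 with an estimated correlation, and 0.265 with the mitochondrial share as a covariate). Other large falls were Reg3b (log2 -2.71), Nrg4 (-2.58), Slc10a6 (-2.39), Itga2 (-2.23), Gadd45b (-2.22) and Mfsd2a (-2.02). The fasting genes Pdk4 (-2.46), Angptl4 (-1.92) and Plin2 (-1.39) fell in the list of fatty acid oxidation and ketogenesis, whose median of -0.10 became 0.17 with scaling by total count (24 genes, 3 fell; 1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.224; adjusted p = 0.853 with an estimated correlation).

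Some hepatocyte genes rose with MSC at 12 h, while 4 broad hepatocyte lists did not pass. Of 19 hepatocyte secreted proteins, 21 cytochrome P450 genes and 23 genes of phase II conjugation and transport 0 passed, and of 21 urea cycle and amino acid genes 1 fell. Their medians were 0.13, 0.06, 0.11 and 0.04 (camera adjusted p = 0.349, 0.298, 0.664 and 0.710). Adjusted over the list alone, 0, 1, 6 and 0 rose and 0, 0, 4 and 1 fell. With scaling by total count 2, 3, 6 and 2 rose and 0 fell, with medians of 0.44, 0.36, 0.40 and 0.31. Aox3, an aldehyde oxidase, had 62.1 ± 35.0 CPM with MSC and 7.90 ± 3.06 CPM without (log2 2.97 ± 0.46, edgeR adjusted p = 0.00834; 0.0784 with the mitochondrial share as a covariate). Slc10a1, the transporter that takes bile acids up from blood, had 86.6 ± 23.2 against 27.5 ± 7.51 CPM (log2 1.66 ± 0.30, edgeR adjusted p = 0.0156). Akr1d1, an enzyme of bile acid synthesis, changed by 1.81. Of 18 bile acid genes these 2 rose, 0 fell and 16 did not pass (6 rose adjusted over the list alone). Their median change was 0.63 (camera adjusted p = 2.6e-04; adjusted p = 0.753 with an estimated correlation). Of 28 complement and coagulation genes 3 rose and 25 did not pass (8 rose and 1 fell adjusted over the list alone). They were Klkb1, F13b and C1qb, with log2 changes of 1.47, 1.55 and 1.63, and the last is also a macrophage gene. The list had a median of 0.33 (camera adjusted p = 3.8e-05; adjusted p = 0.753 with an estimated correlation), and with scaling by total count 8 rose and the median was 0.60. The glucose transporter Slc2a2 (20.6 ± 2.76 against 7.70 ± 3.02 CPM) and the glycogen regulator Ppp1r3b (86.9 ± 24.0 against 28.9 ± 3.83 CPM) rose among 14 genes of gluconeogenesis and glycogen (4 rose and 2 fell adjusted over the list alone; median 0.36, camera adjusted p = 0.222; adjusted p = 0.753 with an estimated correlation). With the mitochondrial share as a covariate 0 genes passed in the bile acid, complement and gluconeogenesis lists, with medians of 0.66, 0.22 and 0.45. Among 18 circadian clock genes 1 rose and 2 fell, Nr1d1 and Bhlhe41 (-1.67 and -1.89), and with the same covariate 0 passed. In this list 2 rose and 3 fell adjusted over the list alone, with a median of 0.04, a mean of -0.19 and a camera adjusted p of 0.242 towards lower values. The steroid dehydrogenases Hsd3b3 (log2 4.03 ± 0.72) and Hsd3b5 (3.66 ± 0.81) and the matrix protein Spon2 (2.58 ± 0.54) rose. Hsd3b3 had 18.5 ± 20.2 against 1.15 ± 0.427 CPM, so with a spread as large as its mean. Without Con A + MSC 12 h replicate 3 the log2 changes were 2.61 (Hsd3b3), 2.78 (Hsd3b5) and 2.22 (Spon2). Hsd3b3 lost its call without Con A 12 h replicate 2 (edgeR adjusted p = 0.0607). Hsd3b5 lost it without each library but Con A + MSC 12 h replicate 1 (from 0.0578 to 0.126), and Spon2 without Con A 12 h replicate 3 or Con A + MSC 12 h replicate 2 or 3 (from 0.0505 to 0.118). Gemin4, listed at 0 in all Con A 12 h libraries, was at least 72.8-fold higher with MSC (floor of 3 counts per library). Ugt1a10 was at least 59.5-fold higher and Ugt1a7c fell (log2 -4.03); both belong to 1 locus whose members share exons, so the counts of each are uncertain. Such floors and ratio intervals cover counting error only. The mesenchymal stromal cell markers gave 4 of 13 genes higher (Col1a1, Cd44, Ly6a and Eng; 6 adjusted over the list alone; 1 with the mitochondrial share as a covariate). The median log2 change was 0.71 (camera adjusted p = 1.5e-04; adjusted p = 0.208 with an estimated correlation).

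At 12 h 582 genes passed, 327 higher and 255 lower with MSC, 43 of them assembled loci; 3146 had an unadjusted p below the threshold. The groups did not overlap in 26.4% of genes, where chance gives 10%. The number passing was 932, 84 and 314 without Con A 12 h replicate 1, 2 or 3 and 1061, 130 and 66 without Con A + MSC 12 h replicate 1, 2 or 3. Dnase1l3, Aox3 and Ugt1a10 kept their call with each library left out; the other genes named here from the 10 largest rises and 10 largest falls lost theirs without at least 1 library. Mt1 lost its call without Con A 12 h replicate 2 (adjusted p = 0.0591) or Con A + MSC 12 h replicate 2 (0.0600) or 3 (0.0697). Mt2 lost it without Con A + MSC 12 h replicate 3 (0.0631). Cd5l lost it without Con A replicate 2 (0.115) or 3 (0.0696) or Con A + MSC replicate 2 (0.0566) or 3 (0.106). DESeq2 gave 1477 genes, a fit of the 12 h libraries alone 135, and the mitochondrial share as a covariate 114. With scaling by total count the median of all genes moved by 0.26 and 829 genes passed, 88.5% of them higher. No gene passed in the same direction at both times (0 higher, 0 lower; 0.0687 and 0.197 by chance), and the log2 changes at 6 h and 12 h had Pearson r = -0.0109 across genes, which are not independent replicates.

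Of the panel at 12 h, Mt1 and Mt2 fell, as did Cdkn1a, a brake on the cell cycle induced by stress (67.7 ± 11.3 against 114 ± 16.6 CPM; log2 -0.75 ± 0.19, edgeR adjusted p = 0.0437). Cdkn1a lost its call with scaling by total count (adjusted p = 0.210) and without Con A replicate 2 (0.144) or 3 (0.0889) or Con A + MSC replicate 1 (0.0765), 2 (0.0764) or 3 (0.181). Ccnd1, a cyclin that drives entry into the cell cycle, had 17.3 ± 5.71 against 6.77 ± 1.22 CPM (edgeR adjusted p = 0.0663) and did not pass. The other log2 differences, none passing, were 1.20 (Ifng), 0.86 (Tnf), 2.17 (Il6, 20 counts against 3), 0.62 (Il1b), -0.27 (Il10), -0.72 (Cxcl1), -1.80 (Cxcl2), 0.12 (Cxcl9), -0.88 (Cxcl10) and -0.35 (Ccl2). They were -0.20 (S100a8), -0.03 (S100a9), -0.54 (Lcn2), -0.38 (Saa1), -0.16 (Saa2), -0.88 (Socs3), -0.22 (Mki67), 0.11 (Hmox1), 0.13 (Alb), 0.06 (Cyp2e1), 2.26 (Cyp7a1), -0.28 (Cyp3a11), -0.02 (Pck1) and -0.09 (Gpx4). Of 23 interferon gamma response genes 1 rose, Serpina3g (log2 1.17), and 22 did not pass (7 rose adjusted over the list alone). The list median was 0.50 (camera adjusted p = 0.00312; adjusted p = 0.753 with an estimated correlation). Without Con A replicate 1 the camera p was 0.144. With scaling by total count 8 rose and the median was 0.80. The type I interferon genes, so much lower with MSC at 6 h, had a median of -0.21 at 12 h (0 of 18 passing, 0 adjusted over the list alone; camera adjusted p = 0.231), and 0.10 with scaling by total count. Cytokines of myeloid cells, lower as a set at 6 h, passed camera as higher at 12 h (0 of 15 passing, 2 rose adjusted over the list alone; median 0.65; camera adjusted p = 0.0295; adjusted p = 0.753 with an estimated correlation). That call ended without Con A 12 h replicate 1 (0.240) or 2 (0.0961), with at least 5 CPM in 3 libraries (0.166) and with scaling by total count (0.0958). Of 13 T cell markers 0 rose and 1 fell (Cd28), also adjusted over the list alone, with a median of 0.73 (camera adjusted p = 0.0487; adjusted p = 0.753 with an estimated correlation). That call ended without Con A 12 h replicate 1 (0.405) or 2 (0.0709) or Con A + MSC 12 h replicate 1 (0.0718) or 2 (0.0993), in a fit of the 12 h libraries alone (0.0848) and with scaling by total count (0.101). In total 17 of 51 lists passed camera at 12 h, 12 higher and 5 lower, and 0 with an estimated correlation (smallest adjusted p = 0.208).

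From 6 h to 12 h without MSC the early inflammatory programme declined. All 18 immediate early genes fell, with a median of -2.60 (18 fell adjusted over the list alone; camera adjusted p = 7.8e-16; adjusted p = 0.0797 with an estimated correlation). Junb, a transcription factor, went from 543 ± 50.1 to 117 ± 21.6 CPM and Ier3 from 175 ± 30.9 to 6.49 ± 2.23 CPM. All 16 NF-kB targets fell, among them Tnfaip3, which shuts NF-kB signalling off (266 ± 56.9 to 15.8 ± 4.13 CPM, log2 -4.07 ± 0.35, edgeR adjusted p = 7.9e-06). Icam1, an adhesion molecule for leukocytes, fell as well (356 ± 15.9 to 82.0 ± 15.8 CPM). Their median was -2.07 (16 fell adjusted over the list alone; camera adjusted p = 1.2e-15), and this was the only list to pass with an estimated correlation (adjusted p = 0.0414). All 15 cytokines of myeloid cells fell (median -3.94), as did 17 of 18 chemokines (median -3.20) and 16 of 19 neutrophil markers (median -2.14), with the same numbers adjusted over the list alone. Their camera adjusted p were 6.3e-10, 3.2e-08 and 1.6e-04, and 0.133, 0.136 and 0.382 with an estimated correlation. Csf3 fell from 1708 counts to 3, a ratio of 659 (95% interval 225 to 3197). Sele, an adhesion molecule of activated endothelium, went from 13.4 ± 4.90 to 0.134 ± 0.118 CPM, and Slamf1 and Cyp2c55 changed by -6.34 and -6.19. Of 18 type I interferon genes 14 fell (14 adjusted over the list alone; median -1.90; camera adjusted p = 4.1e-04; adjusted p = 0.467 with an estimated correlation). Ifit2 had 20.8 ± 19.9 against 794 ± 421 CPM.

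Hepatocyte metabolism changed in the same interval without MSC. Of 21 cytochrome P450 genes, which oxidise drugs and steroids, 18 fell (18 adjusted over the list alone). Their median change was -2.19 (camera adjusted p = 6.3e-10; adjusted p = 0.136 with an estimated correlation). Por, which passes electrons to these enzymes, went from 450 ± 104 to 47.6 ± 13.6 CPM and Cyp2f2 from 925 ± 105 to 203 ± 31.1 CPM. Of 21 genes of the urea cycle and amino acid catabolism 17 fell (1 rose and 18 fell adjusted over the list alone; median -1.80; camera adjusted p = 2.6e-09; adjusted p = 0.178 with an estimated correlation). They included Cps1, the entry enzyme of the urea cycle (1918 ± 529 to 266 ± 47.4 CPM). Cholesterol synthesis was the only list higher at 12 h by camera: 12 of 21 genes rose and 0 fell, with a median of 0.75 (12 adjusted over the list alone; camera adjusted p = 4.1e-04; adjusted p = 0.467 with an estimated correlation). Hmgcs1 went from 76.3 ± 34.0 to 439 ± 108 CPM (log2 2.52 ± 0.40, edgeR adjusted p = 3.2e-04) and Lss from 17.0 ± 2.62 to 83.3 ± 11.2 CPM. Derl3, which helps to clear misfolded proteins, rose from 1.60 ± 1.66 to 74.7 ± 10.2 CPM (log2 5.53 ± 1.05, edgeR adjusted p = 0.00109). Sdf2l1 went from 18.8 ± 13.9 to 219 ± 8.29 CPM and Pdia4 from 93.9 ± 34.4 to 379 ± 100.4 CPM. Within the unfolded protein and integrated stress response 7 of 20 genes rose and 6 fell, and the list did not pass (8 rose and 6 fell adjusted over the list alone; median 0.10; camera adjusted p = 0.267; adjusted p = 0.639 with an estimated correlation). Acute-phase proteins also split, 7 rising and 6 falling of 25: Apcs and Orm1 rose (log2 1.62 and 1.19), and Crp and Steap4 fell (-1.63 and -2.91). The list had a median of -0.01, or 0.27 with scaling by total count (camera adjusted p = 0.880; adjusted p = 0.955 with an estimated correlation).

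From 6 h to 12 h with MSC 17 of 18 immediate early genes fell (17 adjusted over the list alone). The median log2 change was -3.05 (camera adjusted p = 4.4e-23; adjusted p = 0.0602 with an estimated correlation). Of 18 hypoxia and glycolysis genes 15 fell (15 adjusted over the list alone; median -1.68; camera adjusted p = 6.1e-16; adjusted p = 0.0601 with an estimated correlation). Rnd1, a GTPase of the cytoskeleton, went from 353 ± 83.7 to 6.87 ± 2.70 CPM. The vasodilator peptide gene Adm changed by -6.36. Of 23 genes of phase II conjugation and transport 19 fell and 0 rose (19 fell adjusted over the list alone; median -1.83; camera adjusted p = 1.5e-10; adjusted p = 0.201 with an estimated correlation). Of 21 P450 genes 17 fell while 1 rose (1 rose and 19 fell adjusted over the list alone; median -2.06; camera adjusted p = 2.2e-10; adjusted p = 0.174 with an estimated correlation). Nr0b2, a repressor of bile acid synthesis, rose from 2.44 ± 1.51 to 53.4 ± 2.74 CPM (log2 4.45 ± 0.36, edgeR adjusted p = 3.9e-06), and Gjc3 changed by 4.36. Cholesterol synthesis was higher again, with 8 of 21 genes rising and a median of 0.74 (8 adjusted over the list alone; camera adjusted p = 0.00332; adjusted p = 0.639 with an estimated correlation), and 15 rising with scaling by total count. Type I interferon genes did not fall as a list: Zbp1 (99.1 ± 23.0 to 228 ± 16.9 CPM), Bst2 and Ddx58 rose, Ifit2 fell (91.3 ± 31.7 to 18.4 ± 15.0 CPM) and 14 did not pass (2 rose and 1 fell adjusted over the list alone). The list median was 0.17 (camera adjusted p = 0.638; adjusted p = 0.923 with an estimated correlation), and with scaling by total count 7 rose and it was 0.73.

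Over all genes, 7020 passed between 6 h and 12 h without MSC (3479 higher, 3541 lower at 12 h) and 5814 with MSC (2936 higher, 2878 lower). The sets shared 2114 genes higher and 2206 lower, where independence would give 716 and 714, and 31 went in opposite directions; the log2 changes had Pearson r = 0.693 across genes. Scaling by total count moved the median of all genes by 0.28 without MSC and 0.59 with MSC, and raised the share higher at 12 h to 64.6% and 82.5% of the genes passing. By camera 36 of 51 lists passed without MSC (1 higher, 35 lower) and 31 with MSC (1 higher, 30 lower); 1 and 0 passed with an estimated correlation. Some of the largest changes are uncertain. Zfp37, Wdr31, Bspry, Kif12, Tnfsf15 and Tnfsf8 lie in a run of 26 tested neighbours on chromosome 4 in GENCODE M21 (GRCm38). The counts of many genes of this run, though not of all, moved together in single libraries. By group means Wdr31 was at least 239-fold higher at 12 h without MSC and Kif12 at least 60.4-fold higher with MSC. These folds do not hold for each library. Wdr31 had 0.128 CPM in Con A 12 h replicate 1 against 39.9 and 37.5 CPM in replicates 2 and 3. In the same replicate 1 Kif12 and Zfp37 were low as well (0.332 and 0.255 CPM). Kif12 had 1.03 CPM in Con A + MSC 12 h replicate 2 against 10.3 and 8.74 CPM in replicates 1 and 3. Without MSC Kif12 and Zfp37 changed by 8.80 and 8.01 and Tnfsf15 by -6.97. The fall of Tnfsf15 without MSC was seen in each library (4.30, 5.02 and 7.93 CPM at 6 h, 0, 0 and 0.148 CPM at 12 h). With MSC Zfp37, Bspry, Tnfsf15 and Tnfsf8 changed by 6.25, 4.54, -8.83 and -7.01. Tnfsf15 had 44.3 ± 73.0 CPM in Con A + MSC 6 h, nearly all of it in replicate 3. Without that library its change with MSC was -4.46, Tnfsf8 changed by -1.30 (adjusted p = 0.168) and Zfp37 by 5.67 (0.0547), the last 2 not passing. Bspry with MSC lost its call without Con A + MSC 6 h replicate 1 (0.0770), 2 (0.0571) or 3 (0.0913) or Con A + MSC 12 h replicate 1 (0.0706) or 3 (0.0566). Wdr31 without MSC lost its call without Con A 6 h replicate 1 (adjusted p = 0.0759), 2 (0.0779) or 3 (0.0776) or Con A 12 h replicate 2 (0.0618) or 3 (0.0558). Ugt1a7c rose without MSC (log2 5.00) and shares exons with its neighbours.

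**Figure D4:**
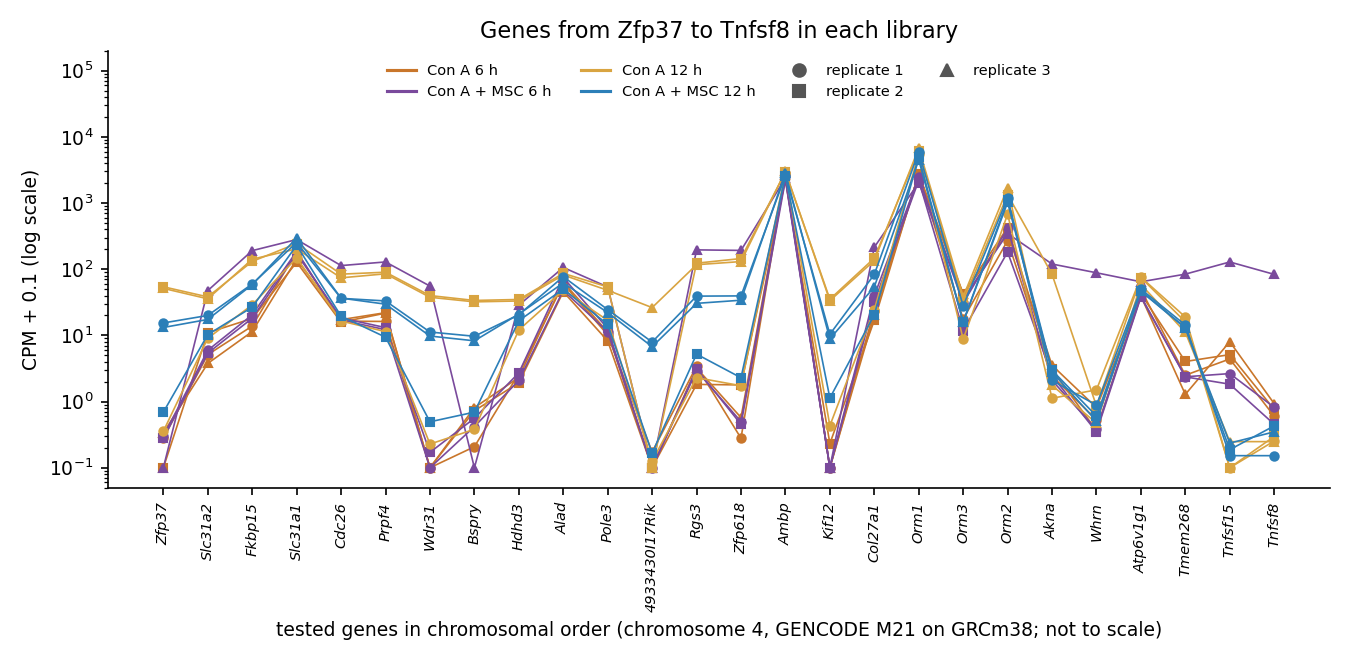
CPM (plus 0.1, log axis) of 26 tested neighbouring genes on chromosome 4 in each library, in chromosomal order in GENCODE M21 (GRCm38) and not to scale; colours give the group and symbols the replicate. The median over the run is 97.1 CPM in Con A + MSC 6 h replicate 3, between 4.15 and 6.59 CPM in the other 6 h libraries and between 10.1 and 64.4 CPM at 12 h.

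In the panel, most cytokine and chemokine genes fell with time in both arms. Without MSC the log2 changes were -3.66 (Tnf), -5.99 (Il6), -3.94 (Il1b), -4.51 (Cxcl2), -2.92 (Cxcl10), -3.46 (Ccl2) and -0.93 (Cxcl9), and with MSC -1.53, -2.07, -2.35, -4.85, -3.57, -2.68 and -0.84, all passing. Ifng, Il10 and Cxcl1 fell without MSC (-2.75, -3.07 and -0.95) and did not pass with MSC (-0.81, -1.30 and -0.80). S100a8, S100a9, Socs3, Cdkn1a, Mki67 and Hmox1 fell without MSC (-1.85, -2.14, -1.42, -1.28, -1.19 and -3.62) and with MSC (-1.44, -1.41, -1.92, -1.38, -1.35 and -3.73). Alb, Cyp2e1, Cyp7a1 and Cyp3a11 fell by a log2 of -1.27, -2.11, -2.74 and -2.24 without MSC and -0.85, -2.20, -2.06 and -2.50 with MSC. The acute-phase genes Saa1 and Saa2 rose (1.25 and 1.05 without MSC, 1.20 and 1.29 with MSC). Mt1 and Mt2 passed only with MSC (-1.57 and -1.65, against 0.30 and 0.07 without), and Ccnd1 and Pck1 only without (-1.93 and -0.65, against -0.25 and -0.22). Lcn2 (0.70 and 0.48) and Gpx4 (0.05 and -0.08) passed in neither. No panel gene passed the test of the difference between the arms; the smallest adjusted p was 0.0883 (Mt2, edgeR).

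The effect of MSC itself differed between 12 h and 6 h in 18 genes, 9 with a larger log2 change at 12 h and 9 with a smaller one; 2401 had an unadjusted p below the threshold. Ccl5, a chemokine for T cells, had 22.3 ± 7.31 (Con A 6 h), 2.45 ± 1.17 (Con A + MSC 6 h), 1.41 ± 0.982 (Con A 12 h) and 5.20 ± 2.97 CPM (Con A + MSC 12 h). The difference of its log2 changes was 5.09 ± 0.84 (edgeR adjusted p = 0.0433). Hpgd, which inactivates prostaglandins, had 133 ± 31.4, 80.6 ± 15.3, 8.18 ± 1.30 and 28.6 ± 4.23 CPM in the same order (2.52 ± 0.30, edgeR adjusted p = 0.00912). Csrp1, a protein of the contractile cytoskeleton, had 33.4 ± 10.3 and 14.1 ± 1.03 CPM at 6 h (without and with MSC) and 4.97 ± 0.558 CPM at 12 h without MSC (2.92 ± 0.36, edgeR adjusted p = 0.00912). The endothelial genes Flt4 (2.00), Plvap (1.36) and Jam2 (1.84) and the lymphocyte gene Gimap4 (1.97) went the same way, with Lmo2 (2.93) and Adprh (1.71). Nat8 (-3.26), Adcy1 (-1.91), Syt12 (-1.83), Tanc2 (-1.77) and Zbtb16 (-1.66) went the other. Gm45717 (-8.30), MSTRG.15211 (-9.50) and MSTRG.17784 (-4.87) went the other way too. The number passing was 97, 8 and 7 without Con A 6 h replicate 1, 2 or 3, 5, 7 and 10 without those of Con A + MSC 6 h, 124, 3 and 120 without those of Con A 12 h, and 131, 8 and 5 without those of Con A + MSC 12 h. Syt12 kept its call with each of the 12 libraries left out. By camera 19 lists passed, 16 with a more positive and 3 with a more negative log2 change with MSC at 12 h than at 6 h. The first by p was type I interferon (median 1.89; 0 of 18 passing, 17 adjusted over the list alone; camera adjusted p = 1.3e-12; adjusted p = 0.442 with an estimated correlation). For type I interferon the median log2 change with MSC was -2.11 at 6 h and -0.21 at 12 h. With an estimated correlation 0 lists passed.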

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

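Chosen only after the result was seen were the tests of a single library, of fewer leukocytes, of a lower share of hepatocytes, of RNA from the injected cells and of the chromosome 4 counts. The tests of GC content and length, of an exchange of libraries and of other splits were chosen before. Bootstrap intervals in this part come from resampling the genes of a list and not the libraries. They treat genes that move together as independent and leave out the spread between libraries.

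The effect of MSC was compared between the time points, and the difference itself was tested in the fit of all 12 libraries (n = 3 per group). It passed for 18 genes. For some of them the differences of the log2 changes (12 h minus 6 h, edgeR) were 5.09 (Ccl5), 2.93 (Lmo2), 2.92 (Csrp1), 2.52 (Hpgd) and 2.00 (Flt4), and -3.26 (Nat8), -1.91 (Adcy1), -1.83 (Syt12) and -1.77 (Tanc2). Without Con A 12 h replicate 2 the calls of Csrp1 and Hpgd ended (edgeR adjusted p = 0.0505 for each). Ccl5, Lmo2, Flt4, Nat8 and Adcy1 each lost their call without Con A 6 h replicate 2 or 3, any Con A + MSC 6 h library, Con A 12 h replicate 2, or Con A + MSC 12 h replicate 2 or 3. The edgeR adjusted p then ran from 0.0785 to 0.154 (Ccl5), 0.0556 to 0.0925 (Lmo2), 0.0606 to 0.154 (Flt4), 0.0518 to 0.0801 (Nat8) and 0.0633 to 0.154 (Adcy1). Tanc2 lost its call without Con A 6 h replicate 3, Con A + MSC 6 h replicate 1 or 2, Con A 12 h replicate 2 or Con A + MSC 12 h replicate 3 (edgeR adjusted p from 0.0586 to 0.0729).

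The same test of the difference between time points passed camera for 19 gene lists, here with their median differences. They were 1.89 (type I interferon response), 0.69 (interferon gamma response), 2.04 (cytokines of myeloid cells), 1.15 (chemokines), 0.92 (type 1 helper T cell and cytotoxic markers), 0.73 (T cell activation) and 0.82 (MHC class II presentation). For cell types they were 1.45 (sinusoidal endothelial), 1.12 (stellate cell and matrix), 1.57 (Kupffer cell) and 0.94 (mesenchymal stromal cell markers), and 0.86 for MSC effector genes. The others were 0.40 (complement and coagulation), 0.65 (necroptosis, pyroptosis and ferroptosis), 3.01 (female-biased liver genes), 0.42 (lipogenesis), -0.32 (ribosomal proteins), -0.42 (immediate early genes) and -0.29 (metallothionein, iron and heme). The last became 0.02 with scaling by total count, and that of immediate early genes became 0.05 with the mitochondrial share as a covariate. With an estimated correlation 0 of the 19 passed (camera adjusted p from 0.360 to 0.793).

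Of these lists 10 lost their camera call without at least 1 library or under another filter, scaling or covariate that was tried with the preset correlation. Without Con A 12 h replicate 1 the camera adjusted p were 0.0840 (T cell activation), 0.125 (type 1 helper), 0.0802 (MHC class II), 0.126 (lipogenesis), 0.0802 (necroptosis), 0.0841 (ribosomal), 0.0841 (female-biased) and 0.177 (MSC effector). Without Con A 6 h replicate 3 they were 0.148 (T cell activation), 0.0690 (type 1 helper), 0.0629 (lipogenesis) and 0.0796 (female-biased), and without Con A + MSC 6 h replicate 2 0.156 (T cell activation) and 0.104 (type 1 helper). For lipogenesis they were also 0.255 and 0.423 without replicate 1 of Con A 6 h and of Con A + MSC 6 h, and 0.0831 and 0.154 without replicate 3 of Con A 12 h and of Con A + MSC 12 h. For immediate early genes they were 0.0888, 0.176, 0.0762, 0.432 and 0.240 without Con A 6 h replicate 1 or 2, Con A + MSC 6 h replicate 1, Con A 12 h replicate 3 or Con A + MSC 12 h replicate 1. T cell activation lost its call also without Con A 12 h replicate 2 (0.163) or Con A + MSC 12 h replicate 2 (0.0697), and ribosomal proteins without Con A 6 h replicate 2 (0.195). With at least 5 CPM in 3 libraries the camera adjusted p was 0.0694 for the Kupffer list, 0.0761 for necroptosis and 0.0737 for MSC effector genes. T cell activation had 0.0509 with no filter, female-biased genes 0.0809 with scaling by total count, and lipogenesis and immediate early genes 0.0851 and 0.891 with the mitochondrial share as a covariate.

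For the difference between the time points 3 of 100 splits, the real one included, gave at least 18 genes, a share of 0.03. The highest other split gave 195 genes, several times the real 18, which points to a structure of the samples that was not tested. The number passing therefore does not single out the real grouping, and chance is not excluded. For the other comparisons the 10 splits are too few for a share under 0.05. The real values and the highest of the other splits were 14 and 1 for MSC at 6 h (1 of 10 splits as large), 582 and 622 at 12 h (2 of 10), 7020 and 0 from 6 h to 12 h without MSC (1 of 10) and 5814 and 0 with MSC (1 of 10). The split with 622 genes exchanges the replicate 1 libraries of the 12 h groups.

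Type I interferon response genes were lower with MSC at 6 h (median log2 difference -2.11 over 18 genes). A single library is argued against, since the median nearest to 0 with each of the 6 libraries left out in turn was -1.45 (without Con A 6 h replicate 2) and the farthest -2.49. GC content or gene length is argued against: the smooth trend of the log2 differences on both, over 13187 genes, was small (SD 0.0514), and with it removed the median was -2.09 (95% bootstrap interval -2.87 to -1.87). Fewer leukocytes in the samples with MSC are argued against, as the whole cause: 80 marker genes of 7 lists had a median of -0.05, 2.07 above the interferon list (interval 1.73 to 2.76), and the lowest lists were B cell (-0.57) and neutrophil markers (-0.54; camera adjusted p = 0.00335, but 0.761 with an estimated correlation, 0.121 without Con A 6 h replicate 3 and 0.192 without Con A + MSC 6 h replicate 2; S100a9 had 34.0 ± 25.8 against 57.2 ± 19.9 CPM), so fewer neutrophils stay open as a part. A weaker or earlier interferon response with MSC may account for the pattern; this stays a hypothesis, found and tested on the same 6 libraries, and a difference in the time of sampling was not tested.

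Endothelial, stellate and Kupffer cell markers were higher with MSC at 12 h (pooled median 1.40 over 47 genes, interval 0.961 to 1.64). From 6 h to 12 h the list medians were lower without MSC (-1.08, -0.86 and -1.90). With MSC they were 0.29, 0.51 and -0.37, or 0.83, 1.05 and 0.18 with scaling by total count. An exchange of the replicate 1 libraries between the 12 h groups is argued against by Con A + MSC 12 h replicate 1 alone. It lay nearer to its own group than to the other by 0.0837 (log2 CPM per gene, a difference of -0.0837). Con A 12 h replicate 1 was nearly as far from its own group as from the other (0.821 and 0.854). Its farthest own library lay at 0.878 and the nearest of the other group at 0.839. Its mitochondrial share was 5.59%, below the mean of Con A + MSC 12 h (7.74%). The split that exchanges both libraries gave 622 genes against the real 582, so an exchange is not excluded. A lower share of hepatocytes raises other cell types alike, and it was tested against neutrophil markers alone. The 3 lists lay 1.51 (interval 1.02 to 1.79) above 19 neutrophil markers (median -0.11). With the mitochondrial share as a covariate the neutrophil median was 0.37 and that of the 3 lists 1.56. Neutrophil RNA can change on its own, so this test cannot decide, and a lower share stays open. B cell (0.77), T cell (0.73), NK cell (0.67), cholangiocyte (0.54), monocyte (0.47) and dendritic cell markers (0.34) had positive medians. Hepatocyte lists were not lower with MSC at 12 h. Their medians were 0.13 (secreted proteins), 0.06 (cytochrome P450), 0.11 (phase II) and 0.04 (urea cycle). RNA of the injected cells could contribute and stays open: 11 mesenchymal stromal cell markers outside the 3 lists had a median of 0.71 (interval 0.0650 to 1.02), with Ly6a at 98.7 against 35.7 CPM and Cd44 at 9.98 against 4.10 CPM, yet the livers without MSC express them too, and at 6 h the full list of 13 was not higher with MSC (median -0.23; Ly6a at 21.2 against 39.9 CPM). A change of these liver cells with MSC is a biological candidate that stays open as well, and with the mitochondrial share as a covariate 5 rather than 17 of the 47 genes rose at a pooled median of 1.56.

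In a run of 26 tested neighbouring genes on chromosome 4, from Zfp37 to Tnfsf8, many but not all rose together in some libraries. From 6 h to 12 h 16 rose and 1 fell without MSC, and 5 rose and 3 fell with MSC. Of the 17 genes that the rule picks by size for the time comparisons 6 lie in the run. Some genes of the run did not follow this joint rise. Ambp hardly changed from 6 h to 12 h (log2 0.20 without and 0.16 with MSC), and Orm1 rose alike in both arms (1.19 and 1.20). Tnfsf15 without MSC was lower in each Con A 12 h library (0, 0 and 0.148 CPM) than in Con A 6 h (4.30, 5.02 and 7.93 CPM). Reads of 1 source spread over neighbouring genes by the counting may explain the joint rise. The counts of Zfp37, Wdr31, Bspry and Kif12 kept 1 ratio over the 4 libraries with at least 100 counts for each. Their chi-square per degree of freedom was 0.0623. Of 1624 other sets of 4 neighbouring genes 0 were as low, with a median of 18.6 and a lowest value of 1.12. Con A + MSC 6 h replicate 3 had the highest run median (97.1 CPM), but with 1554 counts for Wdr31 and 0 for the other 3 genes, so the ratio is not the same in every library. What the source is stays open, and no biological explanation was tested.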

How the results depend on the processing

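Chosen only after the data were seen were scaling by total count alone, the mitochondrial share of each library as a covariate, and the fit without mitochondrially encoded genes; the other settings were chosen before, apart from list tests in some of their fits. In the settings tried, no named gene or passing list turned its direction and stayed past the threshold. DESeq2 size factors within edgeR changed no call of 63 gene results that passed, 59 that did not and 124 list results. The mitochondrial share as a covariate ended 26 of the 63 gene calls. With only the libraries of the groups compared 21 of 51 gene calls ended. The first principal component held 59.2% of the variance, 54.8% with all tested genes and 62.0% with log2(CPM + 0.1). In data simulated at this depth and spread, changes of 1.5-fold, 2-fold and 4-fold were recovered in 4.48%, 32.8% and 75.8% of genes for MSC at 6 h, in 5.97%, 43.3% and 75.8% at 12 h, and in 0%, 0% and 57.6% for the difference of the MSC effect. Small changes were therefore mostly missed in these simulations, in which only 67, 67 and 66 genes per comparison were changed by these folds. Recovery may differ where many more genes change, as from 6 h to 12 h.

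For MSC at 6 h, 14 genes passed. There were 50 with no filter on low counts, 32 with at least 5 CPM in at least 3 libraries (12 shared), 307 with DESeq2 (14 shared), 2 with only the libraries of the groups compared (both higher, so the 11 lower genes lost their calls), 31 with scaling by total count and 64 with the mitochondrial covariate. For MSC at 12 h, 582 passed, against 385 with a 2-fold minimum, 1477 with DESeq2 (578 shared), 135 with only the libraries of the groups compared (122 shared) and 114 with the mitochondrial covariate (85 shared). A 2-fold minimum left 4338 of 7020 genes from 6 h to 12 h without MSC and 3448 of 5814 with MSC. For the difference of the MSC effect 18 passed, against 45 with no filter, 706 with DESeq2 (18 shared), 211 with scaling by total count (18 shared; 187 higher, 24 lower), 9 with the mitochondrial covariate (5 shared) and 11 without mitochondrially encoded genes. The 2-fold minimum loses genes by its construction; for the other settings the cause was not tested.

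With a correlation estimated per list, 0, 0, 1, 0 and 0 lists passed for MSC at 6 h, MSC at 12 h, the time change without and with MSC, and the difference, where 21, 17, 36, 31 and 19 passed with the preset correlation of 0.01. With each library left out in turn the genes passing ranged from 1 to 236 (MSC at 6 h), 66 to 1061 (MSC at 12 h), 5688 to 6834 and 4434 to 5063 (time without and with MSC) and 3 to 131 (difference). The lists ranged from 16 to 20, 12 to 23, 32 to 38, 29 to 33 and 13 to 25. The lowest and highest counts came without Con A + MSC 6 h replicate 3 (and equally Con A 6 h replicate 3) and Con A 6 h replicate 1 for MSC at 6 h. They came without Con A + MSC 12 h replicates 3 and 1 for MSC at 12 h, and without Con A 12 h replicate 2 and Con A + MSC 12 h replicate 1 for the difference. Of 438 such results for named genes that had passed, 271 kept the call and 167 lost it, 7 calls were gained by named genes that had not passed, and calls of lists were kept in 772 and lost in 86.

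With the replicate number as a block (replicate block), 4 genes passed for MSC at 6 h (4 shared) and 313 for MSC at 12 h (300 shared). Of 63 calls of named genes 13 were lost, and 0 of 124 list calls. The numbers do not pair the samples: of 18 pairs of libraries with the same number 1 had a correlation of deviations over 0.1 (r from -0.226 to 0.130, median -0.00409), and 2 of 12 libraries were closest to their own number, which is a hint from the data and not the design.

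Alternatives written for normalized values (pseudocounts, quantile normalization, TMM on values, limma without trend and library weights) did not apply to counts, nor did genes absent from some tables, since the 4 tables hold the same genes. Using only the groups compared is not possible for the difference, which needs all 4 groups, and DESeq2 has no list test. Some named genes and lists had no value under the stricter filter, which removed their genes, and some genes had no adjusted p from DESeq2.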

Other observations

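The gene lists in this part were fixed before the data were examined; the choice of those described here, after. Genes of red blood cells fell from 6 h to 12 h in both arms. Of 10 red blood cell and platelet genes 7 fell without MSC (10 adjusted over the list alone), with a median of -2.46 (camera adjusted p = 0.00142; adjusted p = 0.382 with an estimated correlation). With MSC 8 fell (8 adjusted over the list alone), with a median of -2.38 (camera adjusted p = 0.00193; adjusted p = 0.384 with an estimated correlation). Hbb-bs went from 489 ± 309 to 52.1 ± 23.3 CPM without MSC and from 510 ± 118 to 66.3 ± 15.1 CPM with MSC. Alas2, the first enzyme of heme synthesis in red cells, went from 90.7 ± 35.8 to 25.9 ± 5.00 CPM and from 103 ± 12.5 to 32.4 ± 11.6 CPM. Globin genes took 0.129 ± 0.0755% and 0.143 ± 0.0390% of counts in Con A 6 h and Con A + MSC 6 h, and 0.0208 ± 0.00914% and 0.0293 ± 0.00784% at 12 h.

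Clock genes also changed with time, and the design cannot separate time after Con A from time of day. Without MSC 4 of 18 circadian clock genes rose and 12 fell (the same adjusted over the list alone), with a median of -1.28 (camera adjusted p = 9.9e-04; adjusted p = 0.0797 with an estimated correlation). With MSC 5 rose and 10 fell (the same adjusted over the list alone), again with a median of -1.28 (camera adjusted p = 0.00224; adjusted p = 0.0872 with an estimated correlation). Bhlhe40, a repressor of the clock, went from 723 ± 156 to 63.3 ± 14.1 CPM without MSC and from 694 ± 43.5 to 63.9 ± 26.9 CPM with MSC. Nr1d2, a nuclear receptor of the clock, went from 74.9 ± 12.5 to 18.1 ± 4.25 CPM and from 77.1 ± 9.14 to 13.7 ± 4.11 CPM. Of 17 genes of necroptosis, pyroptosis and ferroptosis 13 fell and 1 rose without MSC (the same adjusted over the list alone), with a median of -1.30 (camera adjusted p = 5.9e-05; adjusted p = 0.239 with an estimated correlation). Ripk1, a kinase of necroptosis, went from 62.1 ± 7.30 to 25.7 ± 1.35 CPM. Of 19 proteins secreted by hepatocytes 14 fell without MSC (15 adjusted over the list alone; median -0.88; camera adjusted p = 4.1e-04; adjusted p = 0.382 with an estimated correlation). With MSC 11 fell (11 adjusted over the list alone; median -0.74; camera adjusted p = 0.00287; adjusted p = 0.530 with an estimated correlation). With scaling by total count 11 fell and 1 rose without MSC (median -0.59), and 2 fell and 3 rose with MSC (median -0.20). Male-biased liver genes fell in 7 of 14 cases without MSC (median -1.02; camera adjusted p = 0.0126; adjusted p = 0.436 with an estimated correlation) and in 11 with MSC (median -1.48; camera adjusted p = 1.3e-04; adjusted p = 0.364 with an estimated correlation; 7 with scaling by total count).

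Female-biased liver genes (11 tested) had a median of -1.18 with MSC at 6 h, where 0 passed (1 fell adjusted over the list alone; camera adjusted p = 0.00354; adjusted p = 0.258 with an estimated correlation); without Con A 6 h replicate 3 the camera adjusted p was 0.0531. At 12 h their median was 0.95, or 0.84 with genes absent from a group at their bound (0 passing; camera adjusted p = 0.662). The 4 sex chromosome genes were not tested as a list; their medians were 0.16 and 0.02 for MSC at 6 h and 12 h, -0.46 and -0.38 for time without and with MSC, and -0.11 for the difference. With scaling by total count the last 2 medians were 0.15 and 0.15 and that for MSC at 12 h was 0.25, or -0.30 with the mitochondrial share as a covariate, so the signs depend on the setting. Cxcl13 had 52 counts in Con A + MSC 12 h and 2 in Con A 12 h, a ratio of 19.6 (95% counting interval 5.16 to 166). Pairs of replicates differed by a chi-square per degree of freedom from 46.3 (Con A + MSC 6 h replicates 2 and 3) to 564 (Con A 12 h replicates 1 and 3).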
